A study of Homo sapiens with 2 samples.

How the data were processed

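RNA sequencing was carried out on T98G, an established human glioblastoma cell line, carrying either a non-targeting control short hairpin RNA (shNT) or a short hairpin RNA against RBBP4 (shRBBP4). Total RNA was extracted with a column kit and libraries were made with a standard Illumina protocol, per the labels' protocols. There were 2 libraries, 1 per group, so no difference between the groups has a replicate check and no p-value is given for a difference between them. Every comparison below sets 1 library against the other and compares those libraries, not the conditions in general.

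The deposited table holds whole-number read counts per gene for each library, and the tools TopHat2 2.0.6, Bowtie and HTSeq are named with the genome builds hg19 and GRCh37 per the submitters' processing notes, with no role, order or counting option given. The version of the gene annotation and the use of strand in the counting are not given in the sources used here. Every deposited count was even (100% of values in both libraries), as it is when both mates of a read pair are counted, so a fragment was taken as 2 counts wherever counting error was computed. The deposited RPKM values (reads scaled by gene length and library size) equal the count divided by the gene length that the authors list as coding length and by 1 constant per library, and the counts assigned to genes made up 88.0% of that constant in shNT and 88.4% in shRBBP4. Of the listed gene lengths, 35.1% were multiples of 3, close to the share for lengths of any kind, so these lengths include untranslated parts. The RPKM values were used for this description alone, and the lengths were used for checks of length bias. Coordinates are those of the deposited table (hg19/GRCh37, start and end of each gene), which carries no exon, intron or strand annotation.

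The table has 23398 lines and 23346 gene symbols. For the 49 symbols listed more than once the line with the most counts was kept, which left out 52 lines. The libraries held 91776306 counts in shNT and 99657418 in shRBBP4. A count of 0 allows up to 3 fragments, which is 0.0650 CPM (counts-per-million) in shNT and 0.0605 CPM in shRBBP4. This floor of 3 fragments per library was used for every lower bound of a fold. A gene was called expressed with at least 1 CPM in at least 1 library, and 1 CPM corresponds to 46.1 fragments in shNT and 49.6 in shRBBP4. Gene types and current names were looked up by symbol and synonym in a RefSeq table of a later assembly, and GC content in transcripts of a later annotation, which gave a value for 96.4% of expressed genes. No coordinate was taken from either.

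Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.01 for shNT and 0.995 for shRBBP4. The ratio of shRBBP4 to shNT is given with a 95% exact conditional (Clopper-Pearson) interval on fragments, and a CPM level with an exact Poisson interval. These intervals and the floor cover counting error only, since fragments without molecular identifiers are not independent molecules and differences between cultures are not included. The log2 ratio was computed with a prior count of 1, scaled by library size. A gene was counted as higher or lower when its ratio was at least 2-fold and the interval excluded 1. Members of gene lists were counted with the same rule at 1.5-fold. By that rule 13.7% of all expressed genes were higher and 11.3% lower, the shares against which counts of list members are to be read.

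In total 48 gene lists (pathways, complexes, cell type markers and signs of RNA quality) with 1280 memberships were fixed, of which 1264 were found in the table, 16 of them under an older symbol. For each list with at least 5 expressed members, the median log2 ratio was set against 10000 random lists of the same size drawn from expressed genes and matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5, which chance gives for 5% of lists whose members vary independently. The percentile describes these libraries, and genes are not replicates. The named genes follow a fixed rule. It takes RBBP4 and its paralog RBBP7, then EP300, CREBBP and MGMT from knowledge of the study's subject whatever their values. It adds the 15 highest and 15 lowest log2 ratios among named protein-coding genes with at least 5 CPM in the higher library and an interval that excludes 1. For each list it takes up to 4 members with the largest absolute log2 ratio, and it takes the 5 genes with the most counts in each library. The grouping, the lists, the thresholds, this rule and all settings but 1, named below, were set before the data were examined. Genes that overlap a named gene are given because of the overlap, other genes named outside the rule are marked as such, and a few that the rule takes are not reported here.

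The alternatives were DESeq2 1.42.0 size factors, total counts and upper-quartile factors in place of TMM, no filter on low counts and a filter of 5 CPM, thresholds of 1.5-fold and 4-fold, an interval wholly beyond 2-fold, protein-coding genes only, the mean of list members in place of the median, removal of a lowess trend (fraction 0.3) on GC content or gene length, and prior counts of 0.5 and 5. A further alternative, chosen after seeing the data, subtracted from each gene the median log2 ratio of its 50 nearest expressed genes on the chromosome. The methods were tested on simulated data made from these libraries, with 200 genes changed among 23346. The changed genes were drawn from those with a mean of at least 2 CPM, so the calls of changed genes do not cover lower levels. In the simulated comparison of shRBBP4 with shNT the 95% interval held the true ratio for 95.0% of genes, 2 of 12438 unchanged expressed genes were called at 2-fold, and all 67 genes changed 3-fold and all 66 changed 8-fold were called, while none of the 67 changed 1.5-fold, which is under the 2-fold threshold, was called. Of 400 random lists without a shift in these simulated counts, 4.25% stood apart. The simulated counts carry counting error only, without differences between cultures and without shifts shared by neighbouring or co-regulated genes. This share therefore need not hold for the real lists. In the real log2 ratios, shuffled over genes within expression bins, lists of 25 members were shifted by 0.2 or 0.4 (log2). Of 200 such lists for each shift, 40.0% and 96.0% stood apart. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. The 13 mitochondrially encoded mRNAs were not analysed here.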

Results

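The transcriptome of T98G glioblastoma cells was profiled in 1 library with a non-targeting control hairpin (shNT) and 1 library with a hairpin against RBBP4 (shRBBP4). RBBP4 is a histone-binding WD-repeat protein shared by several chromatin complexes, and the comparison addresses which transcripts differ when it is depleted, with attention to genes that repair the DNA damage caused by temozolomide. The libraries held 91776306 and 99657418 counts, and 17701 and 17956 genes had at least 1 count. A total of 12830 genes were expressed at 1 CPM or more in at least 1 library, of which 12028 were protein coding. The gene with the most counts in both libraries, without correction for gene length, was COL6A3, a collagen VI chain, at 1.16% of counts in shNT and 1.25% in shRBBP4. It was followed by EEF1A1, FTL, GAPDH and IGFBP5 in shNT and by COL1A2, EEF1A1, PKM2 and FN1 in shRBBP4.

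RBBP4 itself (chromosome 1, 33116749 to 33151812) was lower in the shRBBP4 library, in the direction its label gives. It stood at 177 CPM (173 to 181) in shNT and 83.1 CPM (80.6 to 85.7) in shRBBP4, a ratio of 0.470 (0.453 to 0.488). SYNC, a gene that overlaps RBBP4 in the table, went the other way, from 5.29 to 25.7 CPM. RBBP7, the close paralog that takes the place of RBBP4 in several complexes, had a ratio of 0.693 (0.674 to 0.713). The ratios of these genes have no replicate check, and their intervals cover counting error only.

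MGMT, the methyltransferase that removes O6-alkyl groups from guanine and with them the main toxic lesion of temozolomide, was nearly absent from the shRBBP4 library. MGMT (chromosome 10, 131265454 to 131565783) had 1348 counts in shNT and 4 in shRBBP4, which is 14.6 CPM (13.5 to 15.8) against 0.0403 CPM (0.00489 to 0.146) and a ratio of 0.00276 (0.000334 to 0.0100). The 50 expressed genes nearest to MGMT had a median log2 ratio of 0.16. MGMT was 1 of 60 genes at least 16-fold lower in shRBBP4, so a difference beyond 16-fold was not particular to it. Its log2 ratio of -8.17 was among the lowest of these. Of the 15 genes that the rule took for the lowest ratios, ARMCX2, RPL39L, GPX7 and ITGA4 had lower values (-9.48, -9.26, -9.16 and -8.70). EP300, the histone acetyltransferase p300, differed little, with 163 CPM in shNT and 168 in shRBBP4 and a ratio of 1.03 (1.00 to 1.07). Its paralog CREBBP had a ratio of 0.806 (0.780 to 0.834) in a region with a median log2 ratio of -0.31.

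Subunits of the complexes that contain RBBP4 (NuRD, SIN3, PRC2, CAF-1, NURF and DREAM) did not stand apart as a group. Of 51 expressed members, 1 was at least 1.5-fold higher, 4 were lower and 46 passed neither rule, and the median log2 ratio of -0.06 lay at percentile 25.2 of matched random lists. The largest difference was in E2F5, an E2F transcription factor that works with pocket proteins, at 8.63 CPM in shNT and 0.565 in shRBBP4, which is 15.3-fold lower (10.4 to 23.3) in a region with a median log2 ratio of -0.66. The overlapping C8orf59 went from 40.3 to 25.9 CPM. SMARCA1, the ATPase SNF2L, was 1.95-fold lower, the PRC2 accessory subunit PHF19 1.86-fold lower and E2F4 1.82-fold lower. With regional medians subtracted, E2F4 had a log2 ratio of -0.57, short of 1.5-fold, and SMARCA1 of -0.71. The mean of the members, -0.17, lay at percentile 1.45, where the list would stand apart. None of the 17 histone acetyltransferases and BET proteins passed the 1.5-fold rule, and their median lay at percentile 33.2.

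Homologous recombination genes were lower in the shRBBP4 library as a group. Of 31 expressed members, 8 were at least 1.5-fold lower and 1 was higher, and the median log2 ratio of -0.33 lay at percentile 0.020. RAD54L, a DNA translocase of this pathway, went from 62.5 to 29.9 CPM, a ratio of 0.478 (0.449 to 0.509). The related RAD54B had a ratio of 0.578 and RPA3, the small subunit of the single-strand binding protein RPA, 0.596. These members lay in regions where most genes were lower: the nearest 50 expressed genes had a median log2 ratio of -0.81 around RAD54L, -0.69 around RAD54B and -0.67 around RPA3. With regional medians subtracted, the median of the list was -0.15 at percentile 1.32. LRRC41, which overlaps RAD54L, went from 212 to 104 CPM, and LOC729852, which overlaps RPA3, from 24.6 to 14.8 CPM.

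The other repair pathways with at least 5 expressed genes did not stand apart from matched random lists. Of 13 end-joining genes 3 were lower, namely LIG4 (ligase IV), POLM (polymerase mu) and PRKDC (DNA-PKcs), with ratios of 0.514, 0.523 and 0.653 in regions with medians of -0.38, -0.63 and -0.41, and the list median lay at percentile 51.3. The 3 expressed genes of direct reversal, too few for this comparison, included MGMT and ALKBH2, an alkylated-base dioxygenase with a ratio of 1.29. In the Fanconi anaemia pathway FAN1, a structure-specific nuclease, was 3.80-fold higher and FANCG was 1.59-fold lower among 16 genes, at percentile 18.9. MTMR10, which overlaps FAN1, had a log2 ratio of 2.19. Mismatch repair had MLH3 1.62-fold higher and PMS2 1.62-fold lower among 7 genes, at percentile 49.7, and the medians around MLH3 and PMS2 were 0.24 and -0.71, which leaves log2 ratios of 0.46 and 0.01 once subtracted. Base excision repair had 1 gene higher and 2 lower among 22, at percentile 13.9. The lower ones were MUTYH, an adenine glycosylase, and MPG, the alkyladenine glycosylase, at 2.15-fold and 1.70-fold in regions with medians of -0.81 and -0.45, and each overlaps a gene with a similar ratio (TOE1 and NPRL3). The nucleotide excision repair helicase ERCC2 went from 30.9 to 61.9 CPM and the transcription-coupled repair factor ERCC6 from 8.87 to 22.2 CPM, the only 2 of 18 genes to pass the rule, at percentile 41.7, and both overlap other genes (KLC3 and PGBD3) that were also higher, while FAM21B, which overlaps ERCC6 too, had a log2 ratio of 0.05. Of 18 checkpoint genes 1 was lower, HUS1, a clamp subunit, at a ratio of 0.646 in a region with a median of -0.67, and the list lay at percentile 27.1.

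Across the transcriptome, 890 genes (6.94% of those expressed) were at least 2-fold higher in shRBBP4 and 553 (4.31%) at least 2-fold lower. At 4-fold the counts were 306 and 176, and at 16-fold 62 and 60. The middle of the distribution was narrow, with a median log2 ratio of 0.01 and quartiles of -0.29 and 0.31, and log2 CPM correlated across expressed genes with r = 0.940. These are counts of differences between 2 libraries and include any difference between the cultures.

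**Figure D1:**
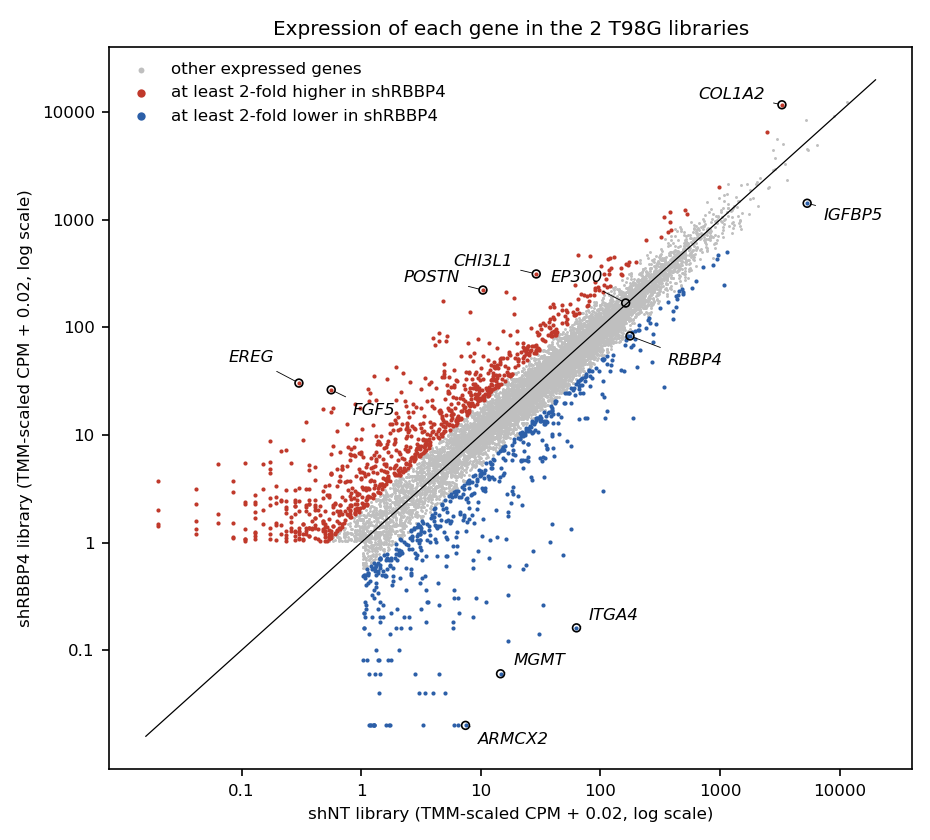
Each point is 1 of 12830 expressed genes, with its TMM-scaled CPM (plus 0.02) in the shNT library on the horizontal log axis and in the shRBBP4 library on the vertical log axis. The 890 genes at least 2-fold higher in shRBBP4 are red and the 553 lower ones blue, and the line marks equal levels, with MGMT far below it and EP300 close to it.

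The 15 genes that the rule took for the lowest ratios, MGMT among them, had 5.01 to 63.1 CPM in shNT and at most 1.31 CPM in shRBBP4. ARMCX2, an X-linked armadillo-repeat gene, RPL39L, a copy of the ribosomal protein gene RPL39 whose reads are uncertain for that reason, and GPX7, a peroxidase of the endoplasmic reticulum, had 7.44, 6.42 and 5.96 CPM in shNT and no count in shRBBP4. Set against the floor of 3 fragments they were at least 123-fold, 106-fold and 98.5-fold lower, and the intervals of their ratios, which also hold the counting error of shNT, reached up to 0.0101, 0.0117 and 0.0126. ITGA4, the integrin alpha 4 chain, went from 63.1 to 0.141 CPM, 447-fold lower (217 to 1112), and the overlapping CERKL from 1.71 to 0.121 CPM. CPE, a prohormone-processing carboxypeptidase, was 253-fold lower (116 to 691). EDNRA, an endothelin receptor, was 166-fold lower, PREX2, an exchange factor for Rac, 137-fold lower, and MAP2, a dendritic microtubule-binding protein, 64.7-fold lower (46.8 to 92.2). PPAPDC3 (now PLPP7) had 5.01 and 0.0202 CPM, a ratio of 0.00403 (0.000102 to 0.0227). The remaining genes of this set were PARP8, MAP7D2, PRSS35, HPGD, which degrades prostaglandins, and SLC6A15, a neutral amino acid transporter, from 55.4-fold to 41.4-fold lower.

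At the other end, EREG (epiregulin), a ligand of the epidermal growth factor receptor, went from 0.282 to 30.3 CPM, 108-fold higher (62.7 to 202), and TGFA, another ligand, from 0.304 to 9.04 CPM, 29.8-fold higher (17.6 to 54.9). EGF, a further ligand of this receptor that was named outside the rule after its values were seen, was 32.4-fold lower (17.3 to 68.2), with 602 and 20 counts. The fibroblast growth factor FGF5 went from 0.542 to 26.2 CPM, 48.4-fold higher (32.6 to 75.1). BAI3 (now ADGRB3), an adhesion receptor, had 0.0434 and 5.39 CPM, a ratio of 124 (34.0 to 1031). ODZ2 (now TENM2), a teneurin, reached 175 CPM from 4.77, 36.6-fold higher (32.0 to 42.0). CAMK1G, the phosphodiesterase PDE1C (in a region with a median log2 ratio of -0.70), the potassium channel KCNQ5, the complement component C7, the semaphorin receptor PLXNA4, the kinase TNIK, the keratin-associated KRTAP1-5, the interferon-induced IFI27 and PSG5, which has near-identical relatives and is uncertain, lay between 28.2-fold and 57.8-fold higher.

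DNA replication genes were lower in the shRBBP4 library as a group. Of 40 expressed S phase genes, 10 were at least 1.5-fold lower and none was higher, and the median log2 ratio of -0.34 lay at percentile 0.00. ORC1, a subunit of the origin recognition complex, went from 71.2 to 35.7 CPM, and MCM7, a subunit of the replicative helicase, from 470 to 242 CPM. The polymerase subunit POLA1 had a ratio of 0.574 and the clamp loader subunit RFC3 of 0.614. The regions around these genes were lower too, with medians of -0.55, -0.32, -0.38 and -0.34. With regional medians subtracted the list median was -0.26, still at percentile 0.00. The count of 10 lower genes was made before this subtraction. After it MCM7 had a log2 ratio of -0.64, while ORC1, POLA1 and RFC3 had -0.44, -0.41 and -0.36, short of 1.5-fold. Of 32 replication-dependent histone genes only 10 were expressed, and the others were under 1 CPM in both libraries. Among the 10, 6 were lower and none higher, at a median of -1.01 and percentile 0.060. Some lay near the filter, such as HIST1H3D at 1.17 CPM and HIST1H2BJ at 2.15 CPM in shNT. These values do not show how histone mRNA as a whole differed. HIST1H2AC went from 12.4 to 4.92 CPM, and HIST1H2BK had a ratio of 0.0367 (0.00741 to 0.112), though these genes have near-identical copies and their reads are uncertain. Of 42 mitosis genes 6 were lower and 2 higher. KIF2C, a microtubule depolymerase, and CDC20, an activator of the anaphase-promoting complex, had ratios of 0.458 and 0.548 in a lowered part of chromosome 1, and the transcription factor MYBL2 was 1.80-fold higher. The mitosis list lay at percentile 6.36, at 1.15 with the mean of the members and at 0.910 with regional medians subtracted.

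Genes of the extracellular matrix were higher in the shRBBP4 library as a group. Of 37 expressed members, 12 were at least 1.5-fold higher and 2 lower, with a median log2 ratio of 0.37 at percentile 100. POSTN (periostin) went from 10.4 to 222 CPM, 21.3-fold higher (19.5 to 23.4), FBLN1 (fibulin 1) from 64.3 to 470 CPM and TNC (tenascin C) from 116 to 432 CPM. The proteoglycan BGN was 5.62-fold lower. Among the genes with the most counts, the collagen I chain COL1A2 went from 3294 to 11693 CPM and fibronectin, FN1, from 2470 to 6544 CPM. The region around COL1A2 had a median log2 ratio of 0.47. Of 6 expressed endothelial and pericyte markers 4 were higher as well, at percentile 98.2, with CSPG4 at 3.41-fold and MCAM at 3.30-fold, and of 7 expressed leukocyte and microglia markers 5 were higher, at percentile 98.5. These marker lists no longer stood apart with the mean of the members (percentiles 91.1 and 85.8) or with no filter on low counts (53.5 and 84.7).

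Proteases and protease inhibitors of the matrix had 11 members higher and 3 lower among 19, at a median of 0.74 and percentile 100. SERPINB2, an inhibitor of plasminogen activators, was 29.1-fold higher (13.9 to 73.3), and the metalloproteases ADAMTS12 and ADAMTS1 were 3.48-fold and 3.40-fold higher, while the stromelysin MMP3 was 4.07-fold lower. Regulators of epithelial-mesenchymal transition and adhesion were split, with 12 higher and 4 lower among 26. The transcription factor PRRX1 was 4.06-fold higher and integrin ITGB3 3.66-fold higher, while ITGA4 and ITGB8 were lower, ITGB8 from 272 to 47.8 CPM in a region with a median of -0.64. The median of this list, 0.53, lay at percentile 100, and its mean, 0.07, at 69.1. Of 24 mesenchymal glioblastoma markers 8 were higher and none lower, at percentile 99.98. CHI3L1, a secreted chitinase-like protein, went from 29.1 to 313 CPM, 10.8-fold higher (10.2 to 11.4), and the AP-1 subunit FOSL2 was 2.52-fold higher. Proneural markers went both ways, with 3 higher and 4 lower among 10 at percentile 74.7 and a mean of -0.08 against a median of 0.15. The oligodendrocyte lineage factor OLIG2 went from 0.542 to 4.42 CPM and the remodeller CHD7 from 11.6 to 0.706 CPM.

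Growth factor genes and their receptors were higher as a group, in 15 of 35 expressed members with 3 lower, at a median of 0.54 and percentile 100. Besides EREG, FGF5 and TGFA, the ephrin EFNB2 went from 3.95 to 80.4 CPM, 20.4-fold higher (17.5 to 23.8). IGFBP5, a binding protein of insulin-like growth factors and 1 of the 5 genes with the most counts in shNT, was 3.76-fold lower (3.73 to 3.79). AP-1 and immediate early genes had 10 members higher and 2 lower among 26, at percentile 99.3. DUSP6 and DUSP1, phosphatases of MAP kinases, were 4.94-fold and 3.17-fold higher, and the zinc-finger factor KLF6 3.06-fold. In TGF-beta and BMP signalling 8 of 24 were higher and 2 lower, with the activin subunit INHBA 9.02-fold higher (6.47 to 12.9) in a region with a median of -0.64 and the receptor TGFBR1 3.75-fold higher, at percentile 99.1 for the median and 97.0 for the mean. YAP and TAZ target genes lay at percentile 98.8, or 97.3 once the trend on gene length was removed. Of 22 such genes 4 were higher and 1 was lower, among them ANKRD1 at 5.31-fold and CTGF (now CCN2) at 2.93-fold higher. NF-kB and inflammatory genes had 8 higher and 3 lower among 24, at percentile 98.5. The cytokine IL1B went from 0.195 to 2.46 CPM and the pentraxin PTX3 from 82.1 to 464 CPM, while IER3 was 7.28-fold lower. With regional medians subtracted this list lay at percentile 92.1, and its mean at 87.3.

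**Figure D2:**
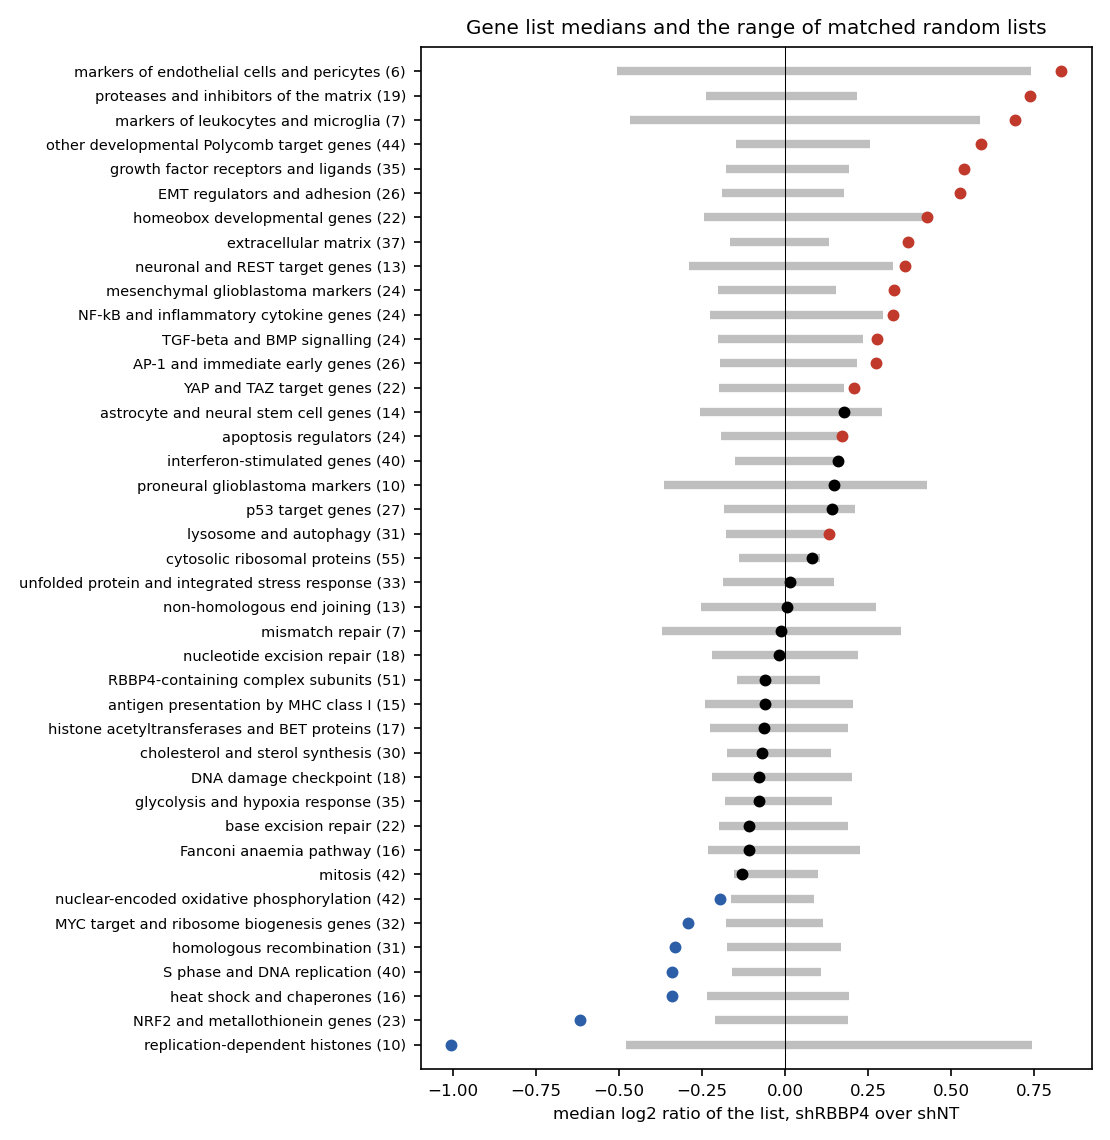
Each dot is the median log2 ratio (shRBBP4 over shNT) of 1 of 41 gene lists, with the number of expressed members in brackets, and each grey bar spans the central 95% of 10000 random lists matched on expression. The 7 lists below their bar are blue and the 16 above it are red. By chance 2.05 lists would lie outside the bars if the members of a list varied independently.

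Developmental transcription factor and signalling genes known as Polycomb targets were higher in the shRBBP4 library as a group. Of 44 such genes 23 were at least 1.5-fold higher and 6 lower, with a median log2 ratio of 0.59 at percentile 100. DLX5, a homeobox factor of bone and forebrain, went from 0.152 to 2.58 CPM, 17.0-fold higher (8.02 to 43.2). The ligand WNT7B went from 2.69 to 19.4 CPM, 7.23-fold higher, and the forkhead factor FOXA2 from 0.629 to 3.75 CPM, while its relative FOXA1 was 6.03-fold lower (5.44 to 6.70). HOX genes, with 8 of 22 higher and 2 lower, lay at percentile 97.6 for the median, 54.1 for the mean, 91.8 with no filter on low counts, 95.8 with the GC content trend removed and 96.8 with regional medians subtracted. HOXC5, which overlaps HOXC4 and HOXC6, and HOXD4 were 2.06-fold and 1.90-fold higher, while HOXA10 and HOXA3, in a region of chromosome 7 with a median of -0.65, had ratios of 0.0282 (0.00334 to 0.106) and 0.525.

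Neuronal genes and targets of the repressor REST went in both directions. Among 13 expressed members 4 were higher and 4 lower, and the median of 0.36 at percentile 98.4 and the mean of -0.32 at percentile 4.74 differ in sign. The list lay at percentile 78.3 with no filter on low counts and at 96.6 with the GC content trend removed. The tau gene MAPT and the synaptic SNAP25 were 3.04-fold and 2.70-fold higher, while MAP2 and the potassium channel KCNH2 were lower, KCNH2 by 3.92-fold. Astrocyte and neural stem cell genes had 4 higher and 2 lower among 14. The Notch target HES1 was 3.07-fold higher and NOTCH3 2.35-fold, while ALDH1A1, a retinaldehyde dehydrogenase, went from 27.1 to 0.807 CPM and the glutamate transporter SLC1A3 was 3.85-fold lower. The median of this list was 0.18 at percentile 88.1 and its mean -0.13, and it lay at 99.6 with regional medians subtracted and at 98.1 with no filter.

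Genes of the NRF2 antioxidant response were lower in the shRBBP4 library as a group. Of 23 expressed NRF2 and metallothionein genes, 15 were at least 1.5-fold lower and 2 higher, with a median log2 ratio of -0.62 at percentile 0.00. GCLC, the catalytic subunit of the enzyme that limits glutathione synthesis, went from 277 to 72.3 CPM, 3.84-fold lower (3.70 to 3.98). The aldo-keto reductase AKR1B10 was 3.37-fold lower, and AKR1C2 2.84-fold, though its reads are uncertain because of near-identical relatives. ME1, the cytosolic malic enzyme, had a ratio of 0.00899 (0.00108 to 0.0329). MYC target and ribosome biogenesis genes were also lower as judged by their median, -0.29 at percentile 0.010. By the 1.5-fold rule 4 of 32 were lower and none higher, while 11.3% of all expressed genes were lower. NIP7, NOP16 and NOP2 had ratios of 0.583, 0.598 and 0.618. NIP7 and NOP2 lay in regions with medians of -0.29 and -0.26 and had log2 ratios of -0.49 and -0.43, short of 1.5-fold, once these were subtracted. Heat shock genes lay at percentile 0.210, with 3 of 16 lower, among them HSPH1 (an HSP110 chaperone) at 0.557 and CHORDC1 at 0.651, with log2 ratios of -0.48 and -0.50 once regional medians were subtracted. Nuclear genes of oxidative phosphorylation lay at percentile 0.850, with 4 of 42 lower (11.3% over all expressed genes), CYCS (cytochrome c), UQCRH, COX6C and UQCRB. The regions around these 4 had medians of -0.68, -0.81, -0.76 and -0.70, and the list lay at percentile 6.18 with regional medians subtracted.

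The log2 ratio was shifted over whole chromosomes and long segments, which hold members of many of the gene groups above. Of 23 chromosomes 17 had a median outside the central 99% of random gene sets of the same size, and 7 differed by at least 0.2 from the median of all expressed genes. Chromosomes 7, 8, 13, 16 and X were lower in their medians, with shifts of -0.43, -0.38, -0.33, -0.32 and -0.25. Chromosomes 14 and 20 were higher, with shifts of 0.30 and 0.29. Not every part of a chromosome followed its median. On chromosome 7 the 75 genes from 90 to 100 Mb had a median of 0.36, and on X the 58 genes from 40 to 50 Mb of 0.09. On chromosome 1 the 364 expressed genes from 0 to 40 Mb, a stretch that holds RBBP4, had a median of 0.08, while the 234 genes from 43 to 100 Mb had a median of -0.56, and 84.2% of them lay below 0. RAD54L, MUTYH, KIF2C, CDC20, ORC1, UQCRH and GPX7 lie in the latter stretch. On chromosome 7 the 201 genes from 0 to 60 Mb had a median of -0.68. On chromosome 15 the 48 genes from 50 to 60 Mb had a median of 0.72 and the 62 genes from 60 to 70 Mb of -0.41. Among windows of 10 Mb with at least 20 expressed genes, 91 of 235 (38.7%) lay outside the central 99%, against 1% by chance. The boundaries of these segments were chosen after the values were seen.

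**Figure D3:**
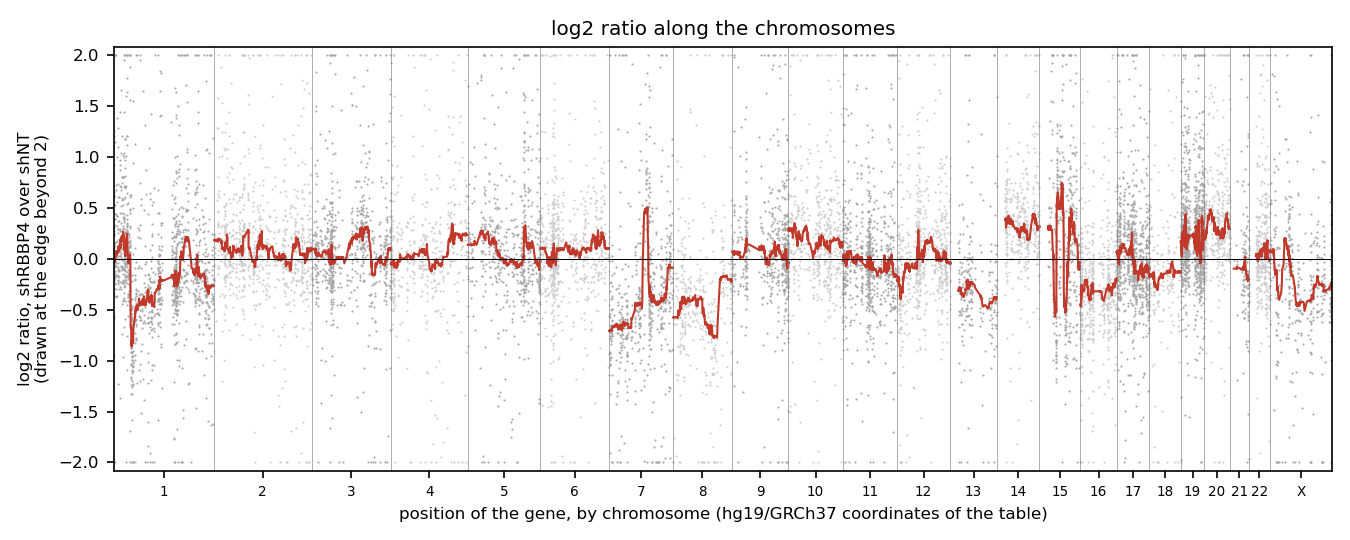
Each grey point is an expressed gene at its position along chromosomes 1 to 22 and X (horizontal axis), with its log2 ratio of shRBBP4 over shNT on the vertical axis, and the red line is the median of the 50 nearest expressed genes. The line steps down within chromosome 1 and runs below 0 along most of chromosomes 7, 8, 13 and 16 and above 0 along 14 and 20.

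Many markers of other cell types were absent or low in both libraries, and among those given here TYROBP, C1QA, CD3E, PTPRC, KDR, PECAM1 and CDH5 were named outside the rule, after their values were seen. The leukocyte genes TYROBP, C1QA and CD3E had no count in either library, which allows up to 0.0650 and 0.0605 CPM, and PTPRC (CD45) stood at 0.195 and 0.141 CPM. Of 20 leukocyte and microglia markers 7 were expressed, 5 of them higher and 1 lower, with LAPTM5 3.04-fold, HLA-DRA 2.44-fold and CD68 2.07-fold higher and ITGAM 3.15-fold lower, at percentile 98.5 for the median, 85.8 for the mean and 84.7 with no filter on low counts. The endothelial receptor KDR had no count, and PECAM1 and CDH5 were under 1 CPM in both libraries. Of 6 expressed endothelial and pericyte markers 4 were higher and 1 lower, with CSPG4 3.41-fold and MCAM 3.30-fold higher, at percentile 98.2 for the median, 91.1 for the mean and 53.5 with no filter. Of 15 epithelial markers 4 were expressed and none passed the 1.5-fold rule. None of the 14 hepatocyte and erythroid markers and none of the 28 cancer-testis genes reached 1 CPM. Of 9 markers of melanocytes, kidney and other lines, PAX8 went from 0.325 to 1.94 CPM and MITF had a ratio of 0.737, and the others stayed under 1 CPM. Among nuclear and non-coding RNAs used as signs of RNA quality, NEAT1 and SNHG1 had ratios of 0.618 and 0.636, and MALAT1 and GAS5 of 0.850 and 0.891.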

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

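The subtraction of regional medians was chosen after seeing the data, and the other settings were planned. RBBP4 was lower under each setting that was run on single genes, at -1.08 to -1.10 under the other scalings and -1.29 with regional medians subtracted. No scaling moved the median log2 ratio of all expressed genes beyond 0.02. Under the planned settings run on single genes (the other scalings and the prior counts of 0.5 and 5) none of the 206 named genes changed direction, and 18 of 1030 values moved beyond the counting interval. Of the 23 lists that stood apart, 12 did so in each setting that gave a value: S phase, homologous recombination, histone, heat shock, MYC, NRF2, matrix, matrix protease, growth factor, AP-1, mesenchymal and Polycomb target lists. With the 5 CPM filter the histone, leukocyte and endothelial lists had fewer than 5 members and gave no value.

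The counts of higher and lower genes depended on the threshold and the filter by construction: 1759 and 1452 at 1.5-fold, 306 and 176 at 4-fold, 569 and 347 with a filter of 5 CPM, and 1273 and 856 with no filter. They were 894 and 547 with DESeq2 size factors, 865 and 578 with total counts, 904 and 545 with upper-quartile factors, 643 and 369 with the interval wholly beyond 2-fold, 822 and 514 for protein-coding genes and 859 and 451 with regional medians subtracted. Genes higher in shRBBP4 outnumbered the lower ones in each.

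The percentiles below crossed the bound for standing apart, and the cause was not tested. With the mean of the members they were 1.45 for RBBP4 complexes, 1.15 for mitosis, 87.3 for NF-kB, 69.1 for adhesion, 97.0 for TGF-beta, 54.1 for HOX, 91.3 for apoptosis, 96.7 for lysosome, 85.8 for leukocyte and 91.1 for endothelial lists, and the neuronal list changed side, to 4.74. With no filter they were 98.1 for astrocyte, 78.3 for neuronal, 91.8 for HOX, 96.0 for apoptosis, 97.3 for lysosome, 84.7 for leukocyte and 53.5 for endothelial lists. With 5 CPM the apoptosis list lay at 96.9 and the lysosome list at 97.3, and with total counts the apoptosis list lay at 97.2. Removing the GC trend gave 98.2 for interferon, 96.6 for neuronal, 95.8 for HOX and 97.3 for apoptosis lists, and removing the length trend gave 97.3 for YAP and 97.49 for apoptosis. Subtracting regional medians gave 0.910 for mitosis, 99.1 for p53, 92.1 for NF-kB, 99.6 for astrocyte, 96.8 for HOX and 6.18 for oxidative phosphorylation.

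The same subtraction moved the log2 ratio of 100 of the 206 named genes beyond its counting interval without a change of direction and left 98 within it. It turned the log2 ratio of 8, by construction close to 0 where a gene moves with its region: PMS2 0.0145, RPL30 0.114, HUS1 0.0465, KAT6A 0.0209, NCOA2 0.00809, CREBBP 0.00467, EEF1A1 -0.00424 and TP53BP1 -0.0153. Depth limits the lowest values: with 2 fragments in shRBBP4, the 95% counting interval of the MGMT ratio spans 0.000334 to 0.0100.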

Other observations

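The tests on shifted chromosomes, on ribosomal protein genes, with the regional shift removed, of GC content for the gene lists, and of the size of regional medians and of GC content and length trends for the 16-fold genes were chosen only after the result was seen, whereas those of neighbouring genes and of chromosome medians were set earlier.

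Interferon-stimulated genes had 9 members higher and 3 lower among 40, at a median log2 ratio of 0.16 and percentile 96.7, or 98.2 with the GC content trend removed. IFI27 was 36.4-fold higher and SAMD9, a restriction factor, 2.27-fold, while the helicase IFIH1 (MDA5), a sensor of double-stranded RNA, was 5.39-fold lower (4.97 to 5.85) and the GTPase MX1 6.08-fold lower. Antigen presentation by MHC class I lay at percentile 36.8, with B2M, its light chain, 1.62-fold higher in a region with a median of 0.60, and the proteasome subunit PSMB10 1.63-fold lower in a region with a median of -0.29. Targets of p53 lay at percentile 90.7, or 99.1 with regional medians subtracted, with 7 of 27 higher, among them the cytokine GDF15 at 3.14-fold and TP53I3 at 2.13-fold, and 2 lower, among them RRM2B at 1.93-fold in a region with a median of -0.76. Apoptosis regulators had 3 of 24 higher (13.7% over all expressed genes), BCL2L1 (1.83-fold), TNFSF10 (1.74-fold) and BCL2 (1.52-fold). The list lay at percentile 97.6 for the median, 91.3 for the mean and between 96.0 and 97.49 in 5 other settings.

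Glycolysis and hypoxia genes were split evenly, with 7 higher and 7 lower among 35 at percentile 21.8. The glucose transporter SLC2A1 went from 446 to 199 CPM in the lowered part of chromosome 1, while SLC2A3 went from 15.9 to 30.3 CPM. Lysosome and autophagy genes lay at percentile 97.8 for the median and 96.7 for the mean. They lay at 97.3 with no filter on low counts or with a filter of 5 CPM. Of 31 members 4 were higher and 2 lower, against 13.7% and 11.3% over all expressed genes. The cholesterol carrier NPC2 was 3.02-fold and the cathepsin CTSZ 2.10-fold higher, while GLA was 1.89-fold and GABARAPL1 1.86-fold lower. Genes of the unfolded protein and integrated stress response lay at percentile 65.1, with the hormone STC2 2.49-fold higher and DDIT4, an inhibitor of mTOR signalling, 3.69-fold lower. Sterol synthesis lay at percentile 25.7, with CYP51A1 1.81-fold higher in a region with a median of 0.45 and the squalene enzymes SQLE and FDFT1 1.55-fold and 1.51-fold lower. SQLE and FDFT1 lay in regions with medians of -0.17 and -0.57 and had log2 ratios of -0.45 and -0.01 once these were subtracted. Cytosolic ribosomal protein genes lay at percentile 93.4, and 2 of 55 passed the 1.5-fold rule, both lower, among them RPL30 in a region with a median of -0.76.

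The shifts along the chromosomes were weighed against 3 explanations. GC content or gene length bias is argued against, since all 7 shifted chromosomes (a share of 1) stayed shifted by at least 0.2 once both trends were removed. For a few strongly changed genes or co-regulated clusters, all 7 (a share of 1) stayed shifted when genes that differ 2-fold or more were left out. This argues against strongly changed genes, though a median over 222 or more genes is little moved by a few of them in any case. Co-regulated clusters that differ by less than 2-fold stayed in the set, so the test cannot decide on them. A difference in DNA dosage between the 2 cell populations is a candidate explanation: the log2 ratio of 55 ribosomal protein genes followed that of their neighbours across genes (Spearman rho = 0.604 and Pearson r = 0.794, permutation p = 0.0001 for both, the smallest that 10000 permutations can give, and r = 0.670 without the 2 farthest genes). Their medians were -0.33 in 7 genes of low regions, 0.09 in 40 genes of middle regions and 0.15 in 8 genes of high regions. The contrast thus came mainly from the low regions. Genes are not independent replicates, no DNA was measured, and a dosage difference may come from the choice of cells, from time in culture or from another origin of the cells, which these tables leave untested.

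For genes at least 16-fold lower, loss of DNA segments in the shRBBP4 population is argued against for most of the 60, because a share of 0.148 (8 of the 54 with an expressed neighbour within 500 kb) had a neighbour at least 4-fold lower, against a mean of 0.0756 in random draws, although the loss of single genes is not excluded. Among the 8, ME1 and PRSS35 are neighbours of each other, and so are CLEC1A and KLRF1, all picked after their values were seen. CLEC1A and KLRF1 had 106 and 146 counts in shNT and 0 in shRBBP4. Loss of a segment is not argued against here for these pairs or for the other genes among the 8. For the 62 genes at least 16-fold higher and loss of DNA in the shNT population the share was 0.464 (26 of 56), above the highest of 100 random draws (0.295) but between the bounds set, so this stays open; clusters such as C6 with C7, ENPP1 with ENPP3 and SERPINB2 with SERPINB7, picked after their values were seen, make up part of it. The test set earlier for a chromosome-scale difference in DNA dosage came out in its favour, with shifted medians on 7 chromosomes, so a part in these differences stays open, but that test did not bear on size. As the whole cause, this difference and the regional shift of the log2 ratio are argued against, since the regional median differed from that of all expressed genes by at most 0.815 around these 122 genes against a log2 ratio of at least 3.86 in size, and so is GC content or gene length bias, whose trends gave at most 0.150 in the 118 genes with values. With 1 library per group, depletion of RBBP4, other effects of the hairpin and differences between cultures remain open and untested as sources of these differences.

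The lists that stood apart were weighed against the regional shift of the log2 ratio. For S phase and DNA replication genes the percentile was 0 with the regional shift removed and the median moved from -0.34 to -0.26, which argues against the regional shift as the whole cause. For developmental Polycomb target genes the percentile was 100 with the regional shift removed (median 0.59 to 0.51) and 100 with the GC content trend removed (0.56), which argues against both. Homologous recombination genes stayed below the bound, at percentile 1.32, but the median went from -0.33 to -0.15, so the part of the regional shift in this list stays open. Depletion of RBBP4 was not tested as an explanation for these lists, since the design has 1 library per group.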
